A study of Sus scrofa with 20 samples.

How the data were processed

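Gene expression was measured by sequencing messenger RNA from the uterus of 20 crossbred sows, with 1 library per sow. The sows were Large White by Landrace crosses, and the semen came from 3 Pietrain boars. Per the labels' protocols, RNA was captured with poly-T beads, made into libraries and sequenced in pairs on an Illumina NovaSeq. The labels' protocols describe both a strand-marking and an unmarked second-strand step, so whether the libraries keep strand is open, and overlapping antisense genes cannot be told apart here. All samples carry the same batch label.

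Per the submitters' processing notes, CASAVA, STAR 2.7.9a and Salmon 1.10.1 were used. The genome build, the annotation release and the strand setting were not given in the sources used here. The deposited values are estimated counts (expected counts) per gene, not scaled to a library total, and 87.2% of them are whole numbers. They were rounded to whole counts before testing. The table has 30369 rows, of which 24 name no gene and were left out; these held between 0.0036% and 0.0133% of each library's counts. Of the 30345 gene rows used, 30328 gene identifiers were found with the same symbol in the RefSeq gene table of assembly Sscrofa11.1, which served for names only. Salmon shares reads between similar transcripts, so values of near-identical genes, such as the ribosomal proteins, the SLA genes and the serum amyloid genes, are uncertain.

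The columns of the table name the group and a number from 1 to 5, whereas the labels number the sows from 1 to 20. The group of each column is therefore known and its sow is not. Libraries are named here by group and column number.

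Groups were compared with edgeR 4.0.16 in R 4.3.3, by the 2-sided quasi-likelihood test on counts with TMM factors. The filter filterByExpr kept 17745 genes. All 20 libraries entered 1 fit, so the 4 groups share 1 estimate of the spread, with 16 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene was called at an adjusted p below 0.05. The fitted fold change compares mean counts, so a single library with a high count can set it. Standard errors are the log2 fold change divided by the square root of the test's F statistic, and levels are TMM-scaled CPM. The comparisons were each inseminated group against control, the inseminated groups against each other, the mean of the 3 inseminated groups against control, and any difference among the 4 groups.

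A set of 31 gene lists with 654 members, 580 of them tested, was fixed together with the tests, the rule for named genes and most alternatives before the data were examined. Each list was tested in each of 7 comparisons, 217 tests in all, with camera from limma 3.58.1 at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. With the estimated correlation no list test passed, and the lowest adjusted p was 0.88. Camera works on log2 values per library, and its direction can differ from that of the fitted fold changes. Named genes are, per comparison, up to 12 higher and 12 lower called genes with the smallest p and a log2 change of at least 1. Where no gene passed, 3 per direction are given as values that did not pass. Up to 4 members with the smallest p were named per list that passed or held a call, and a fixed panel of 12 genes could be given in any comparison.

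Alternatives covered relative log expression factors, DESeq2 1.42.0, limma-voom, 2 other filters on low counts and 2 other thresholds. Further ones used only the libraries of the groups compared, the smooth muscle score or 1 surrogate variable from sva 3.50.0 as a covariate, or left out each library in turn. After the data were seen, limma-voom with a spread per group, an exact rank-sum test over the 15504 sets of 5 libraries, 3 sets of left-out libraries and a split of the controls by column were added. The procedure was tested on simulated counts drawn from the real means, with 200 genes changed by known folds. For all inseminated against control, with 17393 genes, it recovered 53.2% of genes changed 2-fold, 85.9% changed 4-fold and 94.6% changed 8-fold, with 9 false calls. For FR3 against FR1, also with 17393 genes, it recovered 26.6%, 77.8% and 94.5%, with 4 false calls. That simulation gave all groups the same spread, which the control libraries did not have. It also drew each gene on its own, so genes could not move together as they can in real libraries. Its few false calls are therefore no full measure of false calls in these data. Library totals ran from 33 to 62.9 M counts.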

Results

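Uterine tissue was collected 6 days after the onset of estrus from 4 groups of 5 sows. Control sows were not inseminated. The other groups received semen made up of different parts of the boar ejaculate. FR1 held the sperm-rich fraction, FR2 the rich and intermediate fractions, and FR3 the rich, intermediate and poor fractions. The series asks how the fractions deposited change gene expression in the uterus. The uterine horns were separated for embryo verification, but the labels do not say which sows held embryos. In every comparison with control an effect of semen and one of early pregnancy are therefore not separated. Between FR1, FR2 and FR3, unequal numbers of sows with embryos are not excluded either. Total counts per library were 39.9 to 50.9 M in control, 36.4 to 53.9 M in FR1, 39.3 to 47.3 M in FR2 and 33 to 62.9 M in FR3. Between 17006 and 21574 genes had a count above 0 in a library. Of the 190 pairs of libraries, the most alike still differed by a chi-square of 45.9 per gene, so no library was counted as a repeat of another. The control libraries differed more among themselves than the inseminated ones. Their mean pairwise Spearman correlation was 0.902, against 0.957 in FR1, 0.971 in FR2 and 0.951 in FR3, and 21 of 15504 sets of 5 libraries had a mean as low (exact permutation p = 0.00135, 1-sided).

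The first question was which genes differ between inseminated and control sows. Several genes were higher in all 15 inseminated libraries than in any control. FREM1, an extracellular matrix protein of basement membranes, rose from 0.557 ± 0.432 CPM in control (SD, n = 5) to 6.72 ± 3.12 CPM (SD, n = 15), a log2 fold change of 3.54 ± 0.50 (SE, edgeR adjusted p = 0.000246). TRIL, an accessory protein of Toll-like receptor signalling, rose by 3.82 ± 0.55 (adjusted p = 0.000258). SNCAIP rose by 3.08 ± 0.44 and the acid phosphatase ACPP by 3.18 ± 0.46 (adjusted p = 0.000246 and 0.000272). HEYL, a transcription factor downstream of Notch, rose by 1.71 ± 0.27 and GLI1, a transcription factor of hedgehog signalling, by 2.69 ± 0.46 (adjusted p = 0.000449 and 0.000972). PRR16, PAIP2B and MRAS also separated fully, at 1.42 ± 0.21, 1.75 ± 0.28 and 1.19 ± 0.20. DCX and DOPEY2 rose by 1.86 ± 0.29 and 1.30 ± 0.22, with 4 of 5 controls below every inseminated library.

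**Figure D1:**
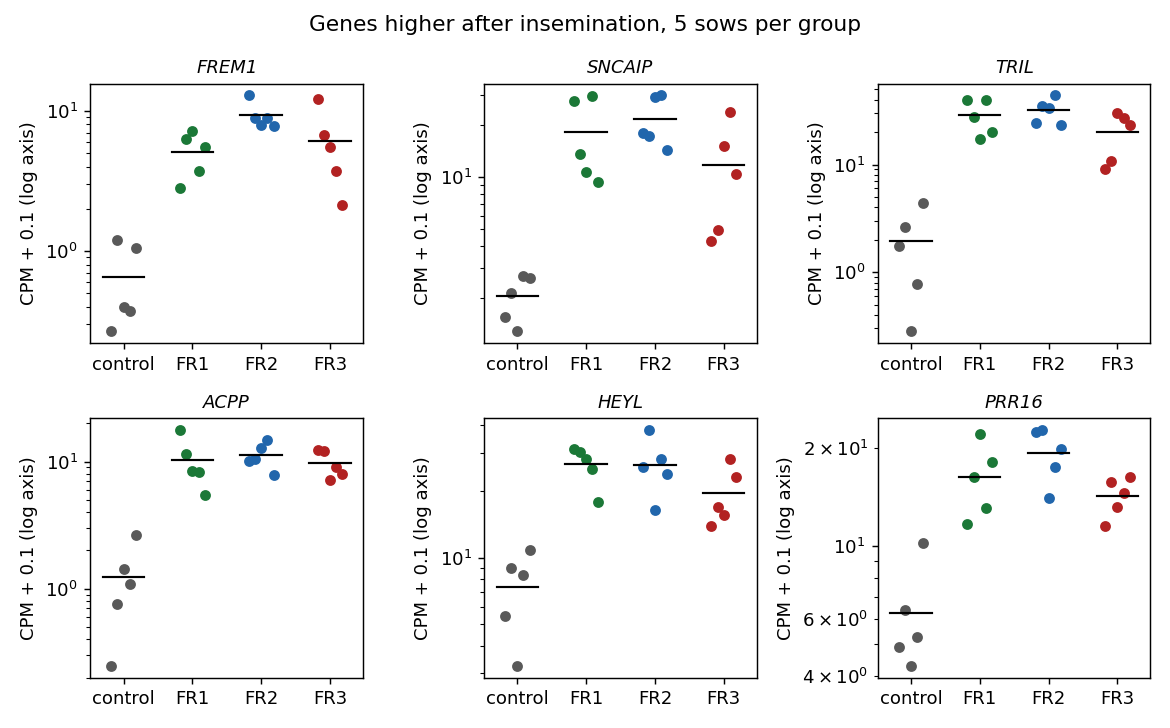
Level of 6 genes in each library (CPM + 0.1, log axis) by group, with 1 point per sow and a line at the group mean. HEYL lay at 13.8 to 37.8 CPM in the 15 inseminated libraries and at 3.14 to 10.7 CPM in the 5 controls.

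Among genes that fell, FXYD3, a regulator of the sodium pump, was above every inseminated library in all 5 controls, at 2.52 to 256 CPM against 0 to 1.67 CPM (log2 -7.35 ± 0.74, edgeR adjusted p = 4.73e-05). KRT18, a keratin of simple epithelia, fell from 348 ± 92 CPM to 149 ± 42.6 CPM (log2 -1.25 ± 0.17, adjusted p = 0.000175), again with all 5 controls above. MPZL2, an adhesion molecule of epithelia, CYP24A1, the enzyme that inactivates vitamin D, and S100A2 fell, at log2 -3.71 ± 0.39, -8.58 ± 0.92 and -3.66 ± 0.40 (each adjusted p = 4.73e-05). For these genes 4 of 5 controls lay above every inseminated library, and CONTROL_5 lay among them at 3.20, 0.278 and 21.3 CPM. VNN2, COL17A1, NOS1, MST1R, ETV4 and CFD fell with the same count of 4 controls, at log2 -9.59, -7.27, -7.73, -2.96, -3.49 and -3.03. The size of several falls leaned on 1 library: without CONTROL_4 VNN2 and COL17A1 were at -7.33 ± 0.78 and -5.57 ± 0.66, without CONTROL_2 NOS1 was at -5.93 ± 0.71, and without CONTROL_3 FXYD3 and MST1R were at -5.88 ± 0.65 and -2.05 ± 0.25, all still called.

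In further genes 1 or 2 control libraries lay far above the rest. SPP1, a secreted phosphoprotein of the uterine glands, was called at log2 -6.56 ± 0.78 (adjusted p = 8.18e-05), with 1350 and 749 CPM in CONTROL_3 and CONTROL_4 and 3.67 to 11.6 CPM in the other controls, against 3.09 to 8.88 CPM in inseminated sows. RBP4, a retinol carrier, was at 2210 and 13100 CPM in CONTROL_2 and CONTROL_3 and at 4.27, 30.9 and 69.9 CPM in the others (log2 -7.52 ± 1.00). FGF7, an epithelial growth factor, was at 398 and 447 CPM in the same libraries and at 0.272 to 3.44 CPM elsewhere in control (log2 -7.03 ± 0.91). DMBT1, a mucosal defence protein, was at 4180 CPM in CONTROL_4 and at 0.301 to 23.7 CPM in the other controls. The exact rank-sum adjusted p was 0.226 for SPP1, 0.298 for RBP4 and 0.57 for FGF7.

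Of 15 tested uterine epithelium markers 8 fell and 0 rose (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000153, and adjusted p = 0.88 with an estimated correlation). These included MUC1 at -3.51 ± 0.48, ELF3 at -3.15 ± 0.39 and the tight junction gene CLDN7 at -0.92 ± 0.17. Of 11 stromal fibroblast markers 2 rose, PDGFRA by 1.55 ± 0.31 and the collagen-binding LUM by 1.42 ± 0.30 (5 adjusted over the list alone; camera adjusted p = 0.000153, and adjusted p = 0.88 with an estimated correlation). COL1A1 and COL3A1 were at 1.17 ± 0.43 and 1.16 ± 0.40 and did not pass. Of 5 mast cell and eosinophil markers MS4A2 and KIT rose, by 1.93 ± 0.53 and 1.09 ± 0.32 (3 adjusted over the list alone; camera adjusted p = 0.0323, and adjusted p = 0.88 with an estimated correlation). These cell type markers were measured in uterine tissue, not in separated cells. A changed share of a cell type and a changed level within it were not told apart.

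Lists of immune genes, and 1 list chosen as a sign of tissue handling, lay lower by camera. All 27 antigen presentation genes had a negative fold change and 10 fell (18 adjusted over the list alone; camera adjusted p = 1.72e-07, and adjusted p = 0.88 with an estimated correlation). PSMB10 and PSMB9, subunits of the immunoproteasome, were at -1.58 ± 0.22 and -1.63 ± 0.36, ERAP1 at -0.84 ± 0.21 and the class I gene SLA-3 at -1.71 ± 0.42. Not called were ERAP1 without CONTROL_4 (-0.60 ± 0.19) and SLA-3 without CONTROL_3 (-0.98 ± 0.38). Without CONTROL_2, CONTROL_3 and CONTROL_4 the list still pointed lower but did not pass (camera adjusted p = 0.0905). That run keeps only CONTROL_1 and CONTROL_5 as controls. CONTROL_3 and CONTROL_4 had the highest means of this list, at 6.71 and 6.39 log2 CPM. Of 30 interferon response genes 5 fell, among them GBP2, GBP1, ISG15 and CXCL10 at -1.71, -1.87, -1.98 and -2.54 (8 adjusted over the list alone; camera adjusted p = 0.00463, and adjusted p = 0.926 with an estimated correlation). CXCL10, GBP1 and GBP2 were at 125, 259 and 61.5 CPM in CONTROL_3 and at 2.12 to 8.47, 11.4 to 32.4 and 6.00 to 6.95 CPM in the other controls. Without CONTROL_3 their log2 values were 0.11 ± 0.53, -0.05 ± 0.32 and -0.29 ± 0.23, not called. ISG15 was at 247 CPM in CONTROL_5 and at 9.81 to 59.5 CPM in the other controls, and at -0.98 ± 0.50 without CONTROL_5, not called. Of 24 inflammatory cytokine genes 6 fell, including IL1A at -6.35 ± 0.97, CXCL2 at -3.24 ± 0.59, ICAM1 at -2.65 ± 0.61 and IL1R2 at -3.58 ± 0.74 (7 adjusted over the list alone; camera adjusted p = 0.0463, and adjusted p = 0.88 with an estimated correlation). IL1R2 was at 28.0 CPM in CONTROL_3 and at 0.179 to 0.608 CPM in the other controls, and ICAM1 and CXCL2 were at 90.1 and 34.8 CPM in CONTROL_4 and at 1.09 to 6.08 and 1.02 to 2.69 CPM in the others. Without that library their log2 values were 0.42 ± 0.48, -0.12 ± 0.44 and -0.78 ± 0.41, not called. Of 22 immediate early and heat shock genes, the list chosen before the data were seen as a sign of RNA quality and handling, 10 fell, among them HSPA6, IER3, JUNB and DNAJB1 at -4.94, -5.48, -2.60 and -1.24 (14 adjusted over the list alone; camera adjusted p = 0.00238, and adjusted p = 0.88 with an estimated correlation). HSPA6 and IER3 were high in CONTROL_2, CONTROL_3 and CONTROL_4. Without CONTROL_3 JUNB was at -1.34 ± 0.39, still called, and DNAJB1 at -0.51 ± 0.15, not called. Without CONTROL_2 and CONTROL_3 the list did not pass (camera adjusted p = 0.666), and without CONTROL_4 as well it turned higher (0.502). Handling and a response of the tissue were not told apart. Of 19 oxidative phosphorylation genes 7 fell, with SDHB, NDUFV1, COX5B and NDUFA1 at -0.69, -0.63, -0.77 and -0.71 (11 adjusted over the list alone; camera adjusted p = 1.24e-05, and adjusted p = 0.88 with an estimated correlation).

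Further lists held calls without passing camera. Of 17 mucosal defence genes 9 fell, MUC4 and SLPI at -6.53 and -5.13 among them (9 adjusted over the list alone; camera adjusted p = 0.0517). SLPI was at 1640 CPM in CONTROL_4 and at 6.82 to 87.3 CPM in the other controls. Of 30 receptivity and histotroph genes 9 fell, IGFBP2 and LIF at -4.08 and -5.18 (13 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.407). IGFBP2 was at 220, 308 and 788 CPM in CONTROL_1, CONTROL_3 and CONTROL_4, and at 6.52 and 9.49 CPM in the other controls, below every inseminated library (10.1 to 38.1 CPM). Of 28 cell adhesion genes 8 fell, the laminin chain LAMB3 at -4.68 and the cytoskeletal linker EZR at -1.05 (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.196). Of 23 complement and acute phase genes 7 fell and 1 rose, SAA3 and CLU at -6.80 and -2.47 (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0864). Of 24 nutrient transporter genes 5 fell and 3 rose, FABP3 at -3.51 and SLC38A1 at 1.17 (7 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.856). In the prostaglandin list PTGES2 and ABCC4 fell, at -0.99 and -1.89, 3 of 21 being called (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.623). In the immune regulation list 2 rose and 2 fell, TGFB3 at 1.87 and IDO1 at -3.64 (2 and 2 adjusted over the list alone; camera adjusted p = 0.812). JCHAIN, of the B and plasma cell list, rose by 1.76 (1 adjusted over the list alone; camera adjusted p = 0.432), and TEAD4, of the early embryo list, fell, at -1.82 (1 adjusted over the list alone; camera adjusted p = 0.659). Smooth muscle, red blood cell, sperm and testis, and steroid response lists held 0 edgeR calls in any comparison, with lowest camera adjusted p of 0.164, 0.129, 0.401 and 0.17.

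Of 21 angiogenesis genes 2 rose and 4 fell, ANGPT2 at 0.95 and VEGFA, DLL4 and ADM at -1.67, -1.71 and -2.92 among them (5 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.108). Of 28 extracellular matrix genes 1 rose and 5 fell, MMP7 and PLAT at -8.37 and -3.72 among them (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.415). CSF3R and MMP8 of the neutrophil list fell, at -3.26 and -4.49 (2 adjusted over the list alone; camera adjusted p = 0.867), and CD14 of the macrophage list at -1.80 (1 adjusted over the list alone; camera adjusted p = 0.895). Several of these values moved far without 1 control library. Without CONTROL_3, where IDO1 was at 7.77 CPM against 0 to 0.356 CPM in the other controls, the log2 values were -0.26 ± 1.01 for IDO1, 0.31 ± 0.45 for CSF3R, 0.05 ± 0.25 for CD14, -0.14 ± 0.43 for ADM and -1.02 ± 0.43 for VEGFA. Without CONTROL_4 they were -1.49 ± 0.50 for SLPI, -3.52 ± 1.19 for MMP7 and 0.57 ± 0.28 for PLAT, without CONTROL_2 -0.77 ± 0.30 for DLL4 and without CONTROL_5 -0.38 ± 0.13 for NDUFA1; none of these was called then. CLU and SAA3 were at -1.32 ± 0.36 and -5.07 ± 1.05 without CONTROL_4, and LIF and FABP3 at -3.33 ± 0.66 and -2.01 ± 0.53 without CONTROL_3, still called. MMP8 was at -3.42 ± 0.89 without CONTROL_2 and at -5.56 ± 0.71 without FR3_5, also still called. Other calls ended with the fold kept and a larger error: TGFB3 and MS4A2 were at 1.75 ± 0.51 and 1.87 ± 0.59 without CONTROL_3, and JCHAIN, KIT and ANGPT2 at 1.57 to 1.68, 0.91 to 1.07 and 0.88 to 0.97 in the 4 runs without a control in which each was not called. The mast cell list did not pass camera without CONTROL_1 (adjusted p = 0.0927) nor the inflammatory cytokine list without CONTROL_4 (0.381), and without FR1_1, FR1_4, FR2_3 and FR3_4 the interferon response list did not (0.594).

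In total 1965 genes were called, 510 higher and 1455 lower, by edgeR, and 83 genes separated all controls from all inseminated libraries where chance gives 2.29 genes (0.0129%). That 2.29 is a mean, and single sets of 5 libraries can lie far above it because genes move together. Of 15504 sets, 26 separated at least 83 genes, the controls included. The set of CONTROL_4, FR1_1, FR1_4, FR2_3 and FR3_4 separated 244. An exact rank-sum test, added after the spread of the controls was seen, called 334 genes, 167 in each direction, of which 318 were among the edgeR calls. Limma-voom with a spread per group called 258. Of the 1455 lower calls, 590 (40.5%) had at most 2 controls above every inseminated library. The count was 988 without CONTROL_3, 2887 by DESeq2 and 1308 by limma-voom, 46.7% of them higher against 26.0% by edgeR.

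**Figure D2:**
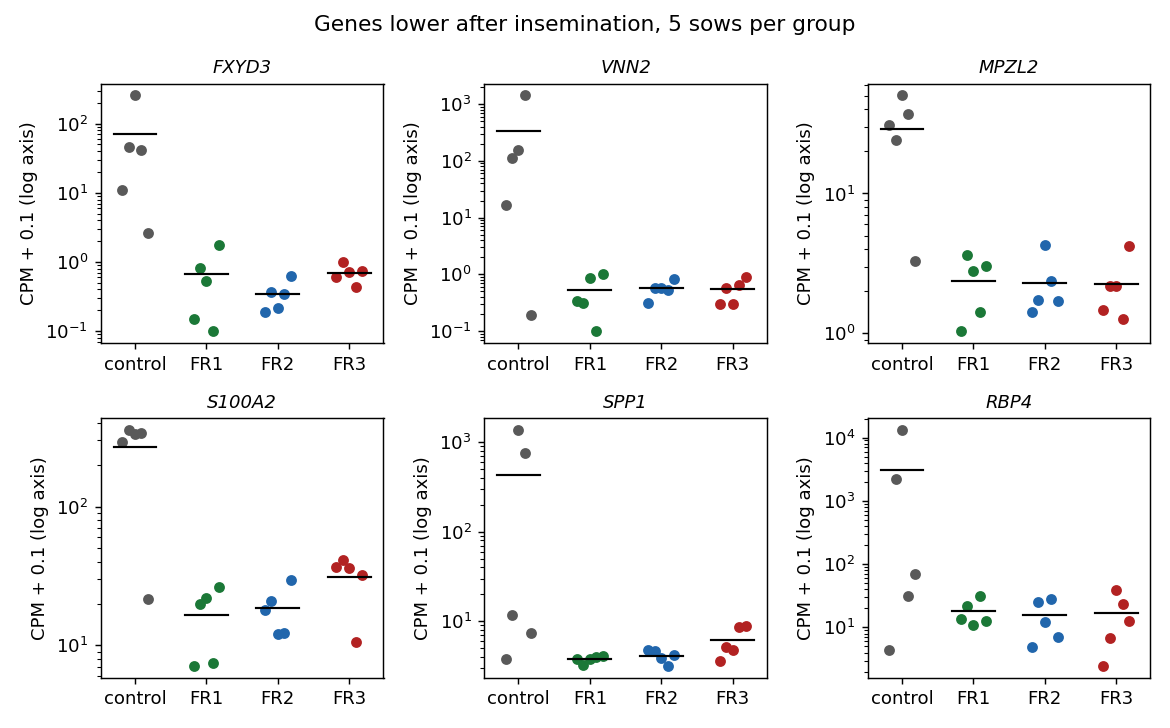
Level of 6 genes in each library (CPM + 0.1, log axis) by group, with 1 point per sow and a line at the group mean. FXYD3 was higher in each control than in any inseminated library, whereas SPP1 was at 1350 and 749 CPM in CONTROL_3 and CONTROL_4 and at 3.67 to 11.6 CPM in the other controls.

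FR1 against control compared sows given the rich fraction alone with sows not inseminated. The genes that rose included TRIL by 3.95 ± 0.59, SNCAIP by 3.20 ± 0.48, FREM1 by 3.17 ± 0.53, ACPP by 3.16 ± 0.50 and HEYL by 1.86 ± 0.30 on the log2 scale (edgeR adjusted p from 0.00746 to 0.00954). DOCK8, SLCO3A1, GLI1, DCX, PRR16 and YPEL1 rose by 2.71, 1.51, 2.82, 1.79, 1.40 and 1.22. S100A2 fell from 268 ± 140 CPM to 16.4 ± 8.79 CPM (SD, n = 5 each, log2 -4.03 ± 0.60, adjusted p = 0.00746). HSPA5, a chaperone of the endoplasmic reticulum, fell at -1.09, S100A1 at -1.77, TAGLN2 at -1.45, PRR5 at -1.31 and KRT18 at -1.38.

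In FR1, of 15 epithelial markers 5 fell, among them MUC1 at -4.17 ± 0.73, ELF3 at -3.28 ± 0.58 and the adhesion molecule EPCAM at -1.06 ± 0.23 (9 adjusted over the list alone; camera adjusted p = 1.21e-05, and adjusted p = 0.88 with an estimated correlation). EPCAM was at 253 to 306 CPM in 4 controls, at 553 CPM in CONTROL_3 and at 159 ± 27.9 CPM in FR1. LUM rose by 1.31 ± 0.34 and was the fibroblast marker called, while PDGFRA was at 1.17 ± 0.35 with adjusted p = 0.0762 (5 adjusted over the list alone; camera adjusted p = 0.000115, and adjusted p = 0.88 with an estimated correlation). All 19 oxidative phosphorylation genes had a negative fold change and SDHB and COX5B fell, at -0.74 and -0.88 (11 adjusted over the list alone; camera adjusted p = 1.28e-08, and adjusted p = 0.88 with an estimated correlation). In antigen presentation PSMB10 and ERAP1 fell, at -1.64 and -1.07 (2 adjusted over the list alone; camera adjusted p = 1.95e-08, and adjusted p = 0.88 with an estimated correlation). The interferon response list was lower with 0 members called, ISG15 at -2.46 ± 0.74 and HERC5 at -1.63 ± 0.46 (0 adjusted over the list alone; camera adjusted p = 1.56e-06, and adjusted p = 0.88 with an estimated correlation). FR1_1 and FR1_4 had means of 3.10 and 2.78 log2 CPM over this list, the other FR1 libraries 4.43 to 5.18 and the controls 3.87 to 5.27; without FR1_1, FR1_4, FR2_3 and FR3_4 the list did not pass (camera adjusted p = 0.15). ISG15 was at -1.46 ± 0.63 without CONTROL_5. The heat shock list was lower too, with 3 members called, HSPA6 and IER3 among them at -4.59 and -5.78 (9 adjusted over the list alone; camera adjusted p = 0.00146, and adjusted p = 0.88 with an estimated correlation). Without CONTROL_3 HSPA6 was at -3.09 ± 0.76 and IER3 at -4.50 ± 1.07, neither called. Without CONTROL_2 and CONTROL_3 the heat shock list did not pass (camera adjusted p = 0.446). The cell cycle list passed camera upward (adjusted p = 0.00558, and adjusted p = 0.926 with an estimated correlation), whereas its median fitted fold change was -0.24 and 0 of 26 members were called; without CONTROL_2 it did not pass (0.32).

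The edgeR count in FR1 was 461, 108 higher and 353 lower. It was 0 by edgeR with only the control and FR1 libraries in the fit (2215 genes at an unadjusted p below 0.05). With all 20 libraries DESeq2 called 1449 and limma-voom 185, 64.9% of the limma-voom calls being higher against 23.4% by edgeR. Leaving out a library gave 107 without FR1_1, 99 without FR1_2, 256 without FR1_3, 142 without FR1_4, 142 without FR1_5, 855 without CONTROL_1, 151 without CONTROL_3 and 1372 without CONTROL_5.

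FR2 against control compared sows given the rich and intermediate fractions with sows not inseminated. The chondroitin synthase CHSY1 rose from 23.7 ± 5.20 CPM to 56.6 ± 8.40 CPM (SD, n = 5 each, log2 1.25 ± 0.16, edgeR adjusted p = 0.00397). FREM1, TRIL, SNCAIP, ACPP and DCX rose by 4.04, 4.09, 3.46, 3.29 and 2.14. SHPRH, PRR16, PAIP2B and HEYL rose by 1.15, 1.65, 1.96 and 1.85. FXYD3 fell at -8.17, S100A2 at -3.86, MPZL2 at -3.71, the complement protease CFD at -3.31, the epithelial transcription factor ELF3 at -3.65 and MST1R at -3.08. KRT18, PRR5, RNH1, S100A1 and ITPK1 fell, at -1.47, -1.42, -1.03, -1.74 and -1.09.

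Of 15 epithelial markers 8 fell (9 adjusted over the list alone; camera adjusted p = 0.000115, and adjusted p = 0.88 with an estimated correlation), including MUC1 and CLDN7 at -3.74 and -1.04. PDGFRA and LUM rose by 2.04 and 1.60 among 11 fibroblast markers (5 adjusted over the list alone; camera adjusted p = 7.27e-05, and adjusted p = 0.88 with an estimated correlation). In the angiogenesis list THBS1, ANGPT2, NRP1 and NOTCH4 rose by 1.54, 1.38, 1.21 and 1.09 among 21 members (5 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0238, and adjusted p = 0.88 with an estimated correlation). THBS1 is known as an inhibitor of vessel growth and NRP1 as a receptor that promotes it. MS4A2 rose by 2.12 ± 0.59 (2 adjusted over the list alone; camera adjusted p = 0.0377, and adjusted p = 0.88 with an estimated correlation). All 19 oxidative phosphorylation genes had a negative fold change and 7 fell, with COX5B, SDHB and NDUFV1 at -1.09, -0.83 and -0.82 (12 adjusted over the list alone; camera adjusted p = 4.49e-09, and adjusted p = 0.88 with an estimated correlation). Of 27 antigen presentation genes 8 fell, PSMB9, SLA-3 and B2M at -2.15, -2.18 and -1.53 among them (11 adjusted over the list alone; camera adjusted p = 4.37e-08, and adjusted p = 0.88 with an estimated correlation). ISG15, at -2.73 ± 0.75, was the interferon response gene called (7 adjusted over the list alone; camera adjusted p = 0.000205, and adjusted p = 0.925 with an estimated correlation). Of 22 heat shock genes 6 fell, HSPA6 and DNAJB1 at -5.32 and -1.71 (9 adjusted over the list alone; camera adjusted p = 0.00903, and adjusted p = 0.88 with an estimated correlation). T and NK cell markers were lower with 0 called (0 adjusted over the list alone; camera adjusted p = 0.0238, and adjusted p = 0.926 with an estimated correlation). The cell cycle list passed upward (camera adjusted p = 0.0157, and adjusted p = 0.926 with an estimated correlation) with a median fitted fold change of -0.17 and 0 members called. Without CONTROL_1 the angiogenesis and mast cell lists did not pass camera (adjusted p = 0.173 and 0.0945), nor did the cell cycle list without CONTROL_2 (0.39), the heat shock list without CONTROL_3 (0.0711) or the T and NK cell list without CONTROL_4 (0.21). Without CONTROL_3 SLA-3 was at -1.44 ± 0.49, not called, and DNAJB1 at -0.98 ± 0.19, and without CONTROL_5 ISG15 was at -1.73 ± 0.64, not called. HSPA6 was at -3.84 ± 0.79 without CONTROL_3, still called.

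The edgeR count in FR2 was 985, 278 higher and 707 lower. It was 1 by edgeR with only the control and FR2 libraries in the fit. With all 20 libraries DESeq2 called 2096 and limma-voom 705, 55.2% of the limma-voom calls being higher against 28.2% by edgeR. Leaving out a library gave 309 without FR2_1, 439 without FR2_2, 510 without FR2_3, 376 without FR2_4, 434 without FR2_5, 425 without CONTROL_3 and 1881 without CONTROL_5.

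FR3 against control compared sows given all 3 fractions with sows not inseminated. FREM1 rose from 0.557 ± 0.432 CPM to 5.96 ± 3.80 CPM (SD, n = 5 each, log2 3.42 ± 0.53, edgeR adjusted p = 0.0106). TRIL, ACPP and SNCAIP rose by 3.42, 3.08 and 2.57. FECH, the last enzyme of heme synthesis, rose by 1.41 and CCL26, a chemokine that attracts eosinophils, by 2.71. MRAS, TTC23, MEGF9, RWDD2A and AGBL2 rose by 1.5, 1.70, 1.17, 1.03 and 1.35. FXYD3, VNN2, CYP24A1, B3GNT7, ETV4, MPZL2 and HACD4 fell, at -6.90, -9.60, -8.95, -4.79, -3.89, -3.75 and -3.18. PRR5, OLFM2, HDAC10, MST1R and UNC5CL fell, at -1.43, -2.42, -1.05, -2.93 and -2.89.

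Of 15 epithelial markers 3 fell, ELF3, KRT18 and MUC1 at -2.53, -0.90 and -2.63 (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0168, and adjusted p = 0.88 with an estimated correlation). FR3_4 had a mean of 5.79 log2 CPM over this list where the other FR3 libraries had 6.89 to 7.15. PDGFRA and LUM rose by 1.46 and 1.33 (2 adjusted over the list alone; camera adjusted p = 0.0184, and adjusted p = 0.88 with an estimated correlation), and MS4A2 by 2.17 (3 adjusted over the list alone; camera adjusted p = 0.0207, and adjusted p = 0.88 with an estimated correlation). PSMB10, at -1.16 ± 0.30, was the antigen presentation gene called (1 adjusted over the list alone; camera adjusted p = 0.00146, and adjusted p = 0.926 with an estimated correlation). CXCL2 and IL1A fell, at -4.30 and -6.72 (5 adjusted over the list alone; camera adjusted p = 0.0301, and adjusted p = 0.88 with an estimated correlation). IL1A was not called without CONTROL_3 (-6.10 ± 1.61, edgeR adjusted p = 0.0621) nor without FR3_2 (-7.87 ± 1.88, edgeR adjusted p = 0.053). HSPA6 and EGR2 fell, at -4.93 and -1.15, with 4 heat shock list members called lower (12 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0219, and adjusted p = 0.903 with an estimated correlation). The ribosomal protein list was higher with 0 of 40 called, RPS2 at 0.84 ± 0.33 (0 adjusted over the list alone; camera adjusted p = 0.0207, and adjusted p = 0.926 with an estimated correlation); without FR3_3 it pointed down with camera adjusted p = 0.905 and RPS2 was at 0.53 ± 0.30. The sterol and fatty acid synthesis list was higher with 0 of 21 called, SC5D at 0.84 ± 0.30 (0 adjusted over the list alone; camera adjusted p = 0.0137, and adjusted p = 0.926 with an estimated correlation). Without FR3_4 the epithelial and fibroblast lists did not pass camera (adjusted p = 0.133 and 0.164), nor did the antigen presentation and heat shock lists without CONTROL_3 (0.14 and 0.237), the inflammatory cytokine list without CONTROL_4 (0.183, with CXCL2 at -1.86 ± 0.52 and not called), the mast cell list without CONTROL_1 (0.0694) or the sterol list without FR3_2 (0.122).

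The edgeR count in FR3 was 758, 253 higher and 505 lower. It was 0 by edgeR with only the control and FR3 libraries in the fit (2182 genes at an unadjusted p below 0.05). With all 20 libraries DESeq2 called 1876 and limma-voom 295, 56.6% of the limma-voom calls being higher against 33.4% by edgeR. Leaving out a library gave 74 without FR3_1, 58 without FR3_2, 475 without FR3_3, 356 without FR3_5, 1377 without CONTROL_1, 214 without CONTROL_3, 452 without CONTROL_4 and 1869 without CONTROL_5. Without FR3_4 it was 867, 416 higher and 451 lower, and without FR1_1, FR1_4, FR2_3 and FR3_4 it was 851, 502 higher and 349 lower, so that most calls were then higher.

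**Figure D3:**
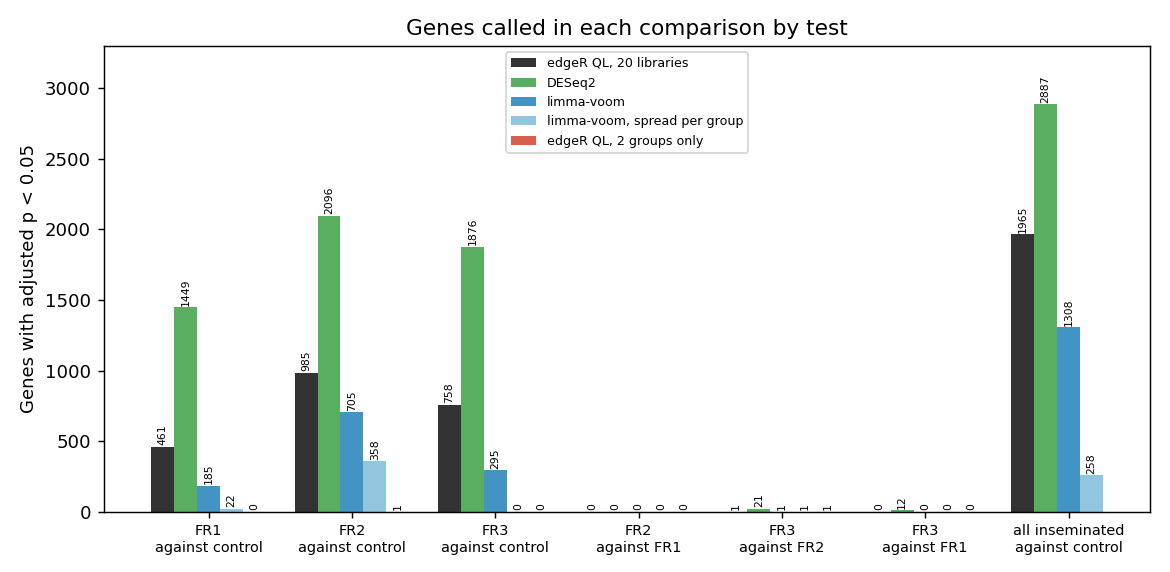
Number of genes with an adjusted p below 0.05 (bars from 0) in each comparison by test. FR1, FR2 and FR3 against control gave 461, 985 and 758 genes by edgeR with all 20 libraries and 0, 1 and 0 with only the groups compared; that setting was not run for all inseminated against control.

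The 3 comparisons against control shared many calls, with the same control libraries in each. FR1 and FR2 shared 411 genes in the same direction, FR1 and FR3 280, and FR2 and FR3 435, and 0 were called in opposite directions by edgeR. Called in all 3 were 273 genes, 53 higher and 220 lower, of 1351 called in any; TRIL, FREM1, SNCAIP and ACPP were among the higher ones and FXYD3 and MPZL2 among the lower ones. Independent lists would share 1.69 higher and 14.1 lower genes for FR1 and FR2, 1.54 and 10.0 for FR1 and FR3, and 3.96 and 20.1 for FR2 and FR3. Simulated unchanged groups against shared controls shared 2.9, 2.7 and 3.05 genes. Each gene was drawn on its own there, so genes could not move together as they can in real libraries. These small counts are therefore no full measure of chance sharing. With the controls split, columns 1 to 3 for one group and 4 and 5 for the other, the shared counts were 179 and 106 for FR1 and FR2, 119 and 93 for FR1 and FR3, and 153 and 175 for FR2 and FR3. Across genes, which are not independent replicates, fold changes correlated at 0.906, 0.771 and 0.799 against simulated values of 0.667, 0.666 and 0.668, and at 0.194 to 0.339 with the controls split. The share of genes with the same sign was 85.0%, 73.9% and 77.0% against simulated shares of 77.1%, 77.1% and 77.3%, so for FR1 and FR3 and for FR2 and FR3 it did not exceed that of unchanged groups. Their covariances were 0.891, 0.791 and 0.828, above the simulated ones by 0.588, 0.490 and 0.527. With the controls split, the covariances were 0.422 and 0.449 for FR1 and FR2, and 0.279 and 0.384 for FR1 and FR3. For FR2 and FR3 they were 0.334 and 0.412. All lay below the values with shared controls, so the excess over the simulation is no measure of what the inseminated groups share.

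FR2 against FR1 asked what the intermediate fraction adds. The genes with the smallest p did not pass: GPCPD1, a glycerophosphocholine phosphodiesterase, was at 0.83 ± 0.21, DCLRE1A at 0.73 ± 0.22 and F2RL2 at 1.06 ± 0.34, and DND1, MAFG and ALOX15 were at -0.98 ± 0.26, -0.50 ± 0.16 and -3.54 ± 1.1 (SE, edgeR adjusted p = 1 for each). The angiogenesis list lay higher in FR2, with 18 of 21 fold changes positive, THBS1 at 1.00 ± 0.34 and ANGPT2 at 0.64 ± 0.32, and 0 members called (0 adjusted over the list alone; camera adjusted p = 0.00516, and adjusted p = 0.88 with an estimated correlation). No gene was called: edgeR gave 0, with 130 genes at an unadjusted p below 0.05 where chance gives 887, and DESeq2 and limma-voom gave 0. The shared spread takes in the controls, whose median dispersion was 0.334 against 0.106 in the inseminated libraries; with only FR1 and FR2 in the fit 567 genes, and by limma-voom with a spread per group 678, had an unadjusted p below 0.05, with 0 called in both.

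FR3 against FR2 asked what the poor fraction adds. GPCPD1 was called, lower in FR3 at 37.9 ± 6.08 CPM than in FR2 at 103 ± 20.5 CPM (SD, n = 5 each, log2 -1.45 ± 0.21, edgeR adjusted p = 0.0278). Its FR3 libraries lay at 28.0 to 42.2 CPM and its FR2 libraries at 82.0 to 136 CPM, while control was at 43.5 ± 10.1 CPM and FR1 at 58.0 ± 17.8 CPM. It was the gene called by edgeR and by limma-voom, with 1307 genes at an unadjusted p below 0.05, while DESeq2 called 21. The call did not hold in most runs with a library left out: edgeR called 0 genes without FR2_1, FR2_3, FR2_4, FR2_5, FR3_1, FR3_3, FR3_4 or FR3_5, with 1068, 797, 1101, 983, 1137, 939, 2169 and 1169 genes at an unadjusted p below 0.05. Without FR3_2 GPCPD1 was not called either, and KRT222, singled out here after its value was seen, was the gene called (log2 -6.90 ± 0.94, adjusted p = 0.0381). In these 9 runs GPCPD1 stayed at log2 -1.33 to -1.52, within 1 SE of the main value, with SE of 0.22 to 0.25 and adjusted p of 0.0653 to 0.194. The fold was kept and fewer libraries left a larger error; the call held without FR2_2.

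Several lists differed between FR3 and FR2 by camera with 0 members called over all genes. All 19 oxidative phosphorylation genes lay higher in FR3, COX7A2 at 0.65 ± 0.18, NDUFA8 at 0.64 ± 0.19 and COX5B at 0.75 ± 0.23 (3 adjusted over the list alone; camera adjusted p = 8.95e-13, and adjusted p = 0.88 with an estimated correlation). All 40 ribosomal protein genes lay higher, RPS28 at 0.70 ± 0.28 and RPS20 at 0.61 ± 0.25 (0 adjusted over the list alone; camera adjusted p = 1.78e-09, and adjusted p = 0.88 with an estimated correlation). The list median was 0.40, and 0.14 without FR3_3, where RPS20 was at 0.37 ± 0.23. Of 30 interferon response genes 28 lay higher, OASL at 3.33 ± 0.93, HERC5 at 1.5 ± 0.46 and ISG15 at 1.99 ± 0.73 (0 adjusted over the list alone; camera adjusted p = 9.84e-09, and adjusted p = 0.88 with an estimated correlation). The list median was 0.85, and 0.40 with 1 surrogate variable, and OASL was at 17.2 CPM in FR3_5 and at 2.13 ± 0.81 without it. Of 26 cell cycle genes 25 lay lower, the kinetochore gene CENPF at -2.78 ± 1.05, MKI67 at -2.34 ± 1.02, CCNE2 at -1.64 ± 0.58 and AURKB at -1.64 ± 0.61 (0 adjusted over the list alone; camera adjusted p = 7.74e-08, and adjusted p = 0.88 with an estimated correlation). Antigen presentation and epithelial lists lay higher, B2M at 1.04 ± 0.41, PSMB10 at 0.78 ± 0.30, KRT18 at 0.56 ± 0.22 and ELF3 at 1.12 ± 0.54 (0 adjusted over the list alone in each; camera adjusted p = 0.00238 and 0.0331, and adjusted p = 0.926 and 0.88 with an estimated correlation). Stromal fibroblast, ciliated epithelium, endothelium and extracellular matrix lists lay lower, with medians of -0.34, -0.46, -0.19 and -0.28 (0 adjusted over the list alone in each; camera adjusted p = 0.021, 0.0233, 0.0449 and 0.0202, and adjusted p = 0.882, 0.903, 0.926 and 0.903 with an estimated correlation). Without FR3_1 these 4 lists and the epithelial one did not pass (camera adjusted p = 0.16, 0.294, 0.494 and 0.134, and 0.104).

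**Figure D4:**
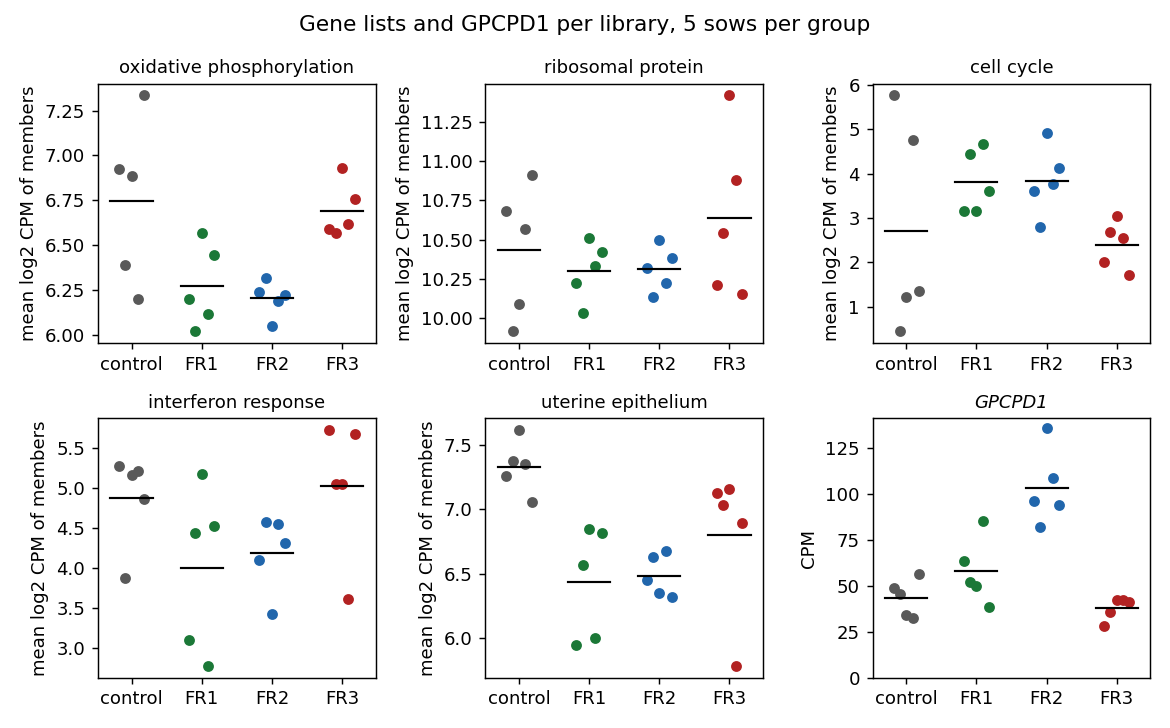
Mean log2 CPM over the members of 5 gene lists, and CPM of GPCPD1, in each library by group, with 1 point per sow and a line at the group mean. GPCPD1 lay at 28.0 to 42.2 CPM in FR3 and at 82.0 to 136 CPM in FR2.

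FR3 against FR1 asked what the intermediate and poor fractions add together. The genes with the smallest p did not pass: FUCA2, a fucosidase, ERP44 and EMC3 were at 1.04 ± 0.26, 0.66 ± 0.16 and 0.78 ± 0.20, and SLC5A9, KIFC2 and SNAPC4 at -5.60 ± 1.06, -1.54 ± 0.31 and -0.79 ± 0.17 (SE, edgeR adjusted p = 0.586 for each). Between FR3 and FR1 edgeR called 0 genes, with 1471 at an unadjusted p below 0.05, DESeq2 called 12 and limma-voom 0.

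Lists were compared with the same FR3 libraries as above, and 0 members were called over all genes. All 19 oxidative phosphorylation genes lay higher in FR3 than in FR1, COX7A2 at 0.56 ± 0.18 and UQCRB at 0.58 ± 0.24 (0 adjusted over the list alone; camera adjusted p = 4.65e-09, and adjusted p = 0.88 with an estimated correlation). All 40 ribosomal protein genes lay higher, RPL27 at 0.59 ± 0.22 and RPS20 at 0.62 ± 0.25 (0 adjusted over the list alone; camera adjusted p = 5.18e-09, and adjusted p = 0.88 with an estimated correlation). The list median was 0.41, and 0.14 without FR3_3, where RPL27 and RPS20 were at 0.38 ± 0.21 and 0.36 ± 0.23. Of 30 interferon response genes 27 lay higher, HERC5 at 1.54 ± 0.46 and OASL at 2.47 ± 0.89 (0 adjusted over the list alone; camera adjusted p = 6.72e-10, and adjusted p = 0.88 with an estimated correlation). The list median was 0.95, and 0.44 with 1 surrogate variable, and OASL was at 1.26 ± 0.80 without FR3_5. FR1_1 and FR1_4 had list means of 3.10 and 2.78 log2 CPM (other FR1 libraries 4.43 to 5.18). FR3_4 had a mean of 3.62 log2 CPM (other FR3 libraries 5.04 to 5.72). Of 26 cell cycle genes 25 lay lower, CCNE2, AURKB, CENPF and PLK1 at -1.58, -1.64, -2.63 and -2.12 (0 adjusted over the list alone; camera adjusted p = 1.39e-07, and adjusted p = 0.88 with an estimated correlation). Macrophage and neutrophil markers lay higher, SPI1 at 0.77 ± 0.33, AIF1 at 0.80 ± 0.41 and MMP8 at 4.57 ± 1.39 (0 and 1 adjusted over the list alone; camera adjusted p = 0.00238 and 0.0381, and adjusted p = 0.88 with an estimated correlation in both). MMP8 was at 14.6 CPM in FR3_5 and at 0.258 to 0.456 CPM in the other FR3 libraries, and at log2 1.35 ± 1.02 without FR3_5; SPI1 was at 0.48 ± 0.33 without FR3_3. The macrophage list did not pass without FR1_1, FR1_4, FR2_3 and FR3_4 (camera adjusted p = 0.296) nor the neutrophil list without FR3_3 (0.125). Epithelial, antigen presentation and sterol synthesis lists lay higher, with medians of 0.43, 0.20 and 0.48, and MUC1 at 1.54 ± 0.66 (0 adjusted over the list alone in each; camera adjusted p = 0.0238, 0.0193 and 0.0251, and adjusted p = 0.88, 0.926 and 0.926 with an estimated correlation). MUC1 was at 21.1 CPM in FR3_5 and at 2.16 to 6.54 CPM in the other FR3 libraries, and at 0.70 ± 0.60 without FR3_5. The sterol synthesis list turned lower with 1 surrogate variable (camera adjusted p = 0.14), and the epithelial list did not pass without FR3_1 (0.077) nor the antigen presentation list without FR1_1 (0.168). The ciliated epithelium list lay lower, with a median of -0.53 (0 adjusted over the list alone; camera adjusted p = 0.0114, and adjusted p = 0.88 with an estimated correlation), and did not pass without FR3_1 (0.185).

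Over all 4 groups, 723 genes differed by the edgeR test of any difference. That count was 204 by limma-voom and 2118 by DESeq2. It was 243 without CONTROL_3, 470 without FR2_1 and 1526 without CONTROL_5.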

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

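The tests of the explanations weighed here, the tests of other groupings of the libraries and limma-voom with a spread per group were chosen only after the results were seen.

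A library was singled out where its gap to the nearest of the 4 others in its group exceeded a fixed share of the group's range. Of 752 such tests on quoted genes and gene list means 57 were met (7.58%), where chance gives about 1 in 20. The set took in CYP26A1 and WNT7A, chosen after the results were seen, and genes such as DMBT1 with ties at 0 CPM. The rate of 1 in 20 is therefore not exact for it. FR2_3 had 11, FR3_4 had 10, CONTROL_3 had 7 and CONTROL_4 and FR3_3 had 5 each.

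In control, CONTROL_3 lay far above the others for SLC2A1 (3390 CPM, others 54.4 to 143), EPCAM (553), CSF3R (77.3), GBP2 (61.5, others 6.00 to 6.95), CD14 (57.8), IL1R2 (28.0) and IDO1 (7.77 CPM). CONTROL_4 lay far above for PLAT (703 CPM, others 4.79 to 10.9), CXCL2 (34.8), CXCL8 (3.88) and SLC5A9 (0.964 CPM), and below for SC5D (22.6 CPM, others 54.4 to 68.4). CONTROL_5 lay far below for S100A2 (21.3 CPM, others 294 to 356) and MPZL2 (3.20 CPM), and above for NDUFA1 (75.1 CPM, others 28.3 to 36.5).

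In FR1, FR1_4 stood apart for the neutrophil list (mean -1.20 log2 CPM, others -0.16 to 0.26), B3GNT7 (6.32 CPM) and TEAD4 (6.45 CPM). FR1_5 did so for the red blood cell list (-0.111 log2 CPM) and GBP1 (37.4 CPM), FR1_3 for IER3 (0.936 CPM), OXTR (1.44 CPM, others 9.68 to 16.2) and RPL27 (444 CPM), and FR1_2 for SNAPC4 (25.4 CPM, others 41.4 to 45.4).

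In FR2, FR2_3 was low for CYP26A1, an enzyme that degrades retinoic acid (0.0957 CPM, others 449 to 1340), for WNT7A (0 CPM, others 94.8 to 154), ABCC4 (7.72), ACP5 (5.38), EDN1 (4.98, others 27.2 to 45.2) and F2RL2 (37.5 CPM). It was high for DOCK8 (93.0), DMBT1 (4.4), MMP7 (24.0) and the progesterone receptor PGR (51.1 CPM, others 27.2 to 31.1), and for the mucosal defence list (1.75 log2 CPM). FR2_1 stood apart for CLDN7 (121), DNAJB1 (50.3) and FREM1 (12.8 CPM), and FR2_5 for CXCL8 (2.39) and IDO1 (0.976 CPM).

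In FR3, FR3_4 was low for the uterine epithelium list (5.79 log2 CPM, others 6.89 to 7.15), the inflammatory cytokine list (0.448), CYP26A1 (87.1 CPM, others 1300 to 3020), WNT7A (11.2 CPM, others 191 to 456), ELF3 (5.84), S100A2 (10.4) and AGBL2 (30.4 CPM). It was high for GLI1 (35.8 CPM, others 9.30 to 12.2), ANGPT2 (9.84) and DMBT1 (0.129 CPM, others 0). FR3_3 was high for SPI1 (25 CPM), CFD (80.7) and PRR5 (21.1) and low for CFB (0.131) and OXTR (0.372 CPM). FR3_2 was high for CXCL8 (1.32 CPM) and FR3_5 for MMP8 (14.6 CPM, others 0.258 to 0.456).

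The first pattern weighed was that the control libraries differed more among themselves than the inseminated ones. A difference in depth is argued against: the highest control total was 1.27 times the lowest, against 1.48 in FR1, 1.2 in FR2 and 1.91 in FR3, and the lowest control total, 39.9 M, was above the lowest of each inseminated group, while the mean Spearman correlation was lowest in control. An uneven share of smooth muscle is argued against as the whole cause: with the smooth muscle score removed the value was 0.918, against 0.967 or more in the inseminated groups. Control sows at different hormonal states remain possible: the SD ratio of control to inseminated libraries had a median of 2.05 over the steroid response list, at the 97.3 percentile of random lists. That test is not specific, since the complement, cell cycle, heat shock, oxidative phosphorylation, receptivity and extracellular matrix lists stood at 99.0 or higher.

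The second pattern was the shift of gene lists in FR3 against FR1. Without FR3_3 the ribosomal protein list kept a share of 0.336 of its median, so a single library may account for much of it. The oxidative phosphorylation list kept at least 0.806 and the cell cycle list at least 0.915 of theirs without any 1 FR3 library, which argues against a single FR3 library there. No FR1 library was left out in that check. Genes of a list moving together from library to library could account for the oxidative phosphorylation call, since camera with an estimated correlation gave an adjusted p of 0.88. The ribosomal protein and cell cycle lists did not pass with an estimated correlation either. An effect of the intermediate and poor fractions together stays open and was not told apart from other differences between the sows.

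The third pattern was that calls against control depend on 1 spread shared by all groups. Limma-voom with a spread per group called 258 genes in all inseminated against control, where limma-voom with 1 spread called 1308, so a spread too small for the control libraries could account for part of the limma-voom calls. For edgeR, which called 1965, no fit with a spread per group was run. The median dispersion was 0.334 in control and 0.106 in the inseminated libraries. With only the groups compared, edgeR called 0, 1 and 0 genes in FR1, FR2 and FR3 against control, in place of 461, 985 and 758. That fit also held fewer libraries, so the spread and the number of libraries were not told apart. No separate biological explanation was tested for this pattern.

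Groupings of the same libraries, 100 per comparison with the real one included, gave a count as large in 1 case for FR1, 1 for FR2 and 5 for FR3 against control. Chance is not excluded for FR3. For FR1 and FR2 the 1 case is the real grouping itself, the lowest number this test can give. The highest other counts were 446, 329 and 1517, against real counts of 461, 985 and 758. Other groupings also mix the controls, which had the larger spread, with inseminated libraries. A difference in mean and one in spread were therefore not told apart. The number was 1 for all inseminated against control (highest other 1494), 1 for any difference among the groups (644) and 1 for FR3 against FR2 (0). For FR3 against FR2 that sets 1 called gene against 0. The number was 100 for FR2 against FR1 and 100 for FR3 against FR1, where edgeR called 0 genes and the highest other counts were 0 and 445. There it was fixed in advance, since no count lies below 0. Of 15504 sets of 5 libraries, 26 separated at least as many genes as the 83 that separated the controls, and the set of CONTROL_4, FR1_1, FR1_4, FR2_3 and FR3_4 separated 244.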

How the results depend on the processing

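The alternatives that leave out sets of libraries, give each group its own spread, use the exact rank-sum test or split the controls were chosen only after the results were seen. The run without CONTROL_2, CONTROL_3 and CONTROL_4 keeps only CONTROL_1 and CONTROL_5 as controls. Of 121 counts recomputed, 67 stayed within 1.5 times and 54 did not. The cause was not tested except where fewer samples or the threshold itself set it. A count of 0 that stayed at 0 is among the 67, so comparisons between inseminated groups add agreements that show little. By limma-voom with a spread per group 3 of 8 counts stayed within, all between inseminated groups, and the 5 that involve controls moved. No paired analysis was possible because each of the 20 sows belongs to 1 group and the labels do not give the boar used for each sow. In the order FR1, FR2 and FR3 against control, counts were 1151, 1918 and 1604 at an adjusted p below 0.10, 1449, 2096 and 1876 by DESeq2, 1007, 1651 and 1326 with the smooth muscle score, and 0, 1 and 0 by edgeR with only the groups compared (2215, 3196 and 2182 at an unadjusted p below 0.05). Limma-voom gave 185 in FR1 and 295 in FR3, 1 surrogate variable 1193 in FR1 and 1930 in FR2, and a log2 change of at least 1 gave 637 in FR2. With a spread per group limma-voom gave 22, 358 and 0 (2101 at an unadjusted p below 0.05 in FR3). Without CONTROL_2 and CONTROL_3 the counts were 174 in FR1 and 505 in FR3, and without CONTROL_4 as well 208, 420 and 7. Without FR1_1, FR1_4, FR2_3 and FR3_4 they were 22 in FR1, 95.5% of them higher, and 474 in FR2. FR3 against FR2 gave 21 by DESeq2 and 0 by edgeR without those 4 libraries (1339 at an unadjusted p below 0.05), and FR3 against FR1 gave 12 by DESeq2. All inseminated against control gave 2980 at 0.10, 1096 with a log2 change of at least 1, 1308 by limma-voom, 258 with a spread per group, 334 by the exact rank-sum test, 1171 without CONTROL_2 and CONTROL_3 and 523 without CONTROL_4 as well. Any difference gave 1304 at 0.10, 2118 by DESeq2, 204 by limma-voom, 1208 with 1 surrogate variable, 22 with a spread per group, 265 and 73 without those control sets and 446 without FR1_1, FR1_4, FR2_3 and FR3_4.

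Leaving out 1 library gave 99 to 1372 in FR1, 309 to 1881 in FR2, 58 to 1869 in FR3, 0 to 1 in FR3 against FR2, 988 to 2730 in all inseminated and 243 to 1526 for any difference; FR2 against FR1 and FR3 against FR1 stayed at 0 by edgeR. List tests passing were 54 of 217, 45 to 65 with 1 library left out, 47 to 57 in other settings, 0 by camera with an estimated correlation, 6 by fry and 29 by fry in either direction. With the controls split, shared calls were 179 and 106 for FR1 and FR2, 119 and 93 for FR1 and FR3, and 153 and 175 for FR2 and FR3.

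Of 287 gene values followed, 194 kept direction and side of the threshold under limma-voom, 263 under DESeq2, 285 under relative log expression and 133 with a spread per group, and with only the groups compared 51 of 192 did. Reversals of sign came with controls left out, which removes the libraries that were high. In all inseminated against control without CONTROL_2, CONTROL_3 and CONTROL_4, log2 values became 0.25 for GBP1, 0.42 for CXCL10, 0.57 for IL1R2, 0.035 for ICAM1, 0.20 for SAA3, 0.027 for SLPI, 0.94 for FGF7, 0.13 for HSPA6, 0.45 for IER3, 0.52 for PLAT, 1.31 for CSF3R, 0.11 for CD14 and 0.66 for ADM, none past the threshold. Without CONTROL_2 and CONTROL_3 they were 0.19 for IL1R2, 0.69 for CSF3R and 0.13 for CD14. With 1 library left out CXCL10 ranged from -2.85 to 0.11, IL1R2 from -3.88 to 0.42, PLAT from -4.08 to 0.57, CSF3R from -3.58 to 0.31 and CD14 from -2.06 to 0.0524. Without CONTROL_2, CONTROL_3 and CONTROL_4, FR1 gave 0.58 for FGF7, 0.50 for HSPA6 and 0.16 for IER3, and FR3 gave 0.16 for SPP1, 0.90 for FGF7 and 0.14 for HSPA6.

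Camera directions also turned. With 1 surrogate variable smooth muscle lay higher in FR3 against FR2 and FR1 (adjusted p = 0.00419 and 0.00396) and sterol synthesis lower in FR3 against FR1 (0.14). Without CONTROL_2 and CONTROL_3, cell cycle lay lower in FR1, FR2 and all inseminated (0.287, 0.339 and 0.008), and in FR3 heat shock lay higher (0.987) and ribosomal proteins lower (0.409). Without CONTROL_4 as well, heat shock lay higher in FR1, FR2, FR3 and all inseminated (0.654, 0.642, 0.234 and 0.502), extracellular matrix higher in FR3 (0.00297) and ribosomal proteins lower in FR3 (0.166). Without FR1_1, FR1_4, FR2_3 and FR3_4, epithelium and interferon response lay lower in FR2 against FR1 (0.0106 and 0.000274). With 1 library left out, smooth muscle in FR3 against control ranged from 0.0473 to 0.89 and ribosomal proteins from 2.25e-05 to 0.905, turning without CONTROL_1 and FR3_3. The cause of these turns was not tested.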

Other observations

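The values here were chosen for description only after the results were seen.

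FR1_1, FR1_4, FR2_3 and FR3_4 shared low values of CYP26A1 and WNT7A. CYP26A1, a retinoic acid hydroxylase, was at 42.4, 0, 0.0957 and 87.1 CPM in these libraries and at 449 to 3020 CPM in the other inseminated ones. WNT7A, a ligand made by uterine epithelium, was at 4.58, 0, 0 and 11.2 CPM, against 94.8 to 456 CPM in the other inseminated ones. The same libraries had the lowest interferon response means of the inseminated ones, at 3.10, 2.78, 3.43 and 3.62 log2 CPM (others 4.10 to 5.72). Their sterol synthesis means were lowest too, at 6.14, 5.99, 6.34 and 5.67 log2 CPM (others 6.74 to 7.90). Uterine epithelium means were 5.95, 6.005, 6.35 and 5.785 log2 CPM (others 6.321 to 7.153). Smooth muscle means were 9.275, 9.096, 8.393 and 9.43 log2 CPM (others 6.80 to 8.725), so FR2_3 lay within the others for both lists. The early embryo means, over 7 members at low levels, were lowest, at -1.749, -1.655, -1.723 and -2.366 log2 CPM (others -1.024 to 0.5033). No explanation for this grouping was tested, a different share of tissues included.

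The cell cycle list varied most among the controls, with means of 5.77 and 4.76 log2 CPM in CONTROL_1 and CONTROL_4 and of 0.45, 1.21 and 1.35 in CONTROL_2, CONTROL_3 and CONTROL_5. MKI67 was at 163 and 93.2 CPM in the former and at 0.92, 4.54 and 2.20 CPM in the latter. The smooth muscle list had a mean of 5.10 log2 CPM in CONTROL_1 and of 8.06 to 9.29 in the other controls, and TAGLN was at 361 CPM there against 4220 to 8750 CPM.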
